A study of Mus musculus with 10 samples.

How the data were processed

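RNA was extracted with a column kit from whole cells of the dissociated deep cervical lymph nodes of each mouse, and heavy- and light-chain libraries were made with a commercial mouse B cell receptor kit that adds unique molecular identifiers, per the labels' protocols. Such kits amplify from the constant region after template switching, so a heavy-chain sequence carries its constant gene. The authors deposited 1 table per mouse in the AIRR layout, per the file headers, with a row per assembled sequence, its V, J and constant gene calls, its alignment to germline and a whole-number count per sequence. The aligner, assembler, their versions, the germline set and the treatment of the molecular identifiers are not given in the sources used here. The count deposited by the authors is therefore called the deposited count, without saying whether it stands for reads or molecules. No normalisation by the authors was visible in these counts, whose totals differed between mice. Plasma cells hold far more receptor transcript than resting B cells, so shares of counts weigh secreting cells, and shares of clonotypes weigh each rearrangement equally. Both were therefore computed.

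Groups were taken from the treatment label and replicate numbers from the sample titles: 5 isotype mice and 5 anti-CTLA-4 mice. All 109 heavy-chain, 112 kappa and 3 lambda gene names in the files matched names in the GRCm38.p6 gene table used here, which served for names alone. No genome was used here and no coordinates are given. Constant genes Ighg2a and Ighg2c, which are alternatives at 1 locus between strains, were summed as IgG2a/c. Heavy-chain sequences that matched several IgG genes (0.308% on average of productive heavy-chain sequences, n = 10) counted as IgG but as no subclass, and those with no constant gene (0.186%) were left out of class shares. Sequences marked as non-productive, 12.3% ± 0.629 of sequences (SD, n = 10), were left out of all comparisons. V calls that named several genes (7.12% of heavy-chain sequences) were kept as joint names, because near-identical V genes cannot be parted by these sequences.

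Clonotypes were distinct combinations of V call, J gene, junction nucleotides and constant gene within a mouse. V mutations were counted as mismatches between the aligned query and germline sequences over at least 200 aligned V nucleotides, per 100 nucleotides, with gaps left out, using the most counted sequence of each clonotype. Hotspots were the C of WRC and the G of GYW in the germline sequence. Lineages joined clonotypes of a mouse with the same first-listed V gene, J gene and junction length at 90% or more junction nucleotide identity by single linkage. Clonotype numbers and evenness were means of 100 random draws at the depth of the shallowest mouse (158989 heavy-chain counts, or 11093 counts for IgG). Overlap was the Morisita-Horn index over V gene and CDR3 amino acid clonotypes, each weighted by its number of clonotypes, at 20886 clonotypes per mouse.

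One value per mouse was compared between groups by a two-sided exact permutation test of the difference of means over all reassignments of the 10 mice, with Benjamini-Hochberg adjustment within families of 9 composition measures (by clonotypes and again by counts), 6 mutation measures, 4 diversity measures, 2 lineage measures, 18 V families and lists, 4 J genes, 2 CDR3 lengths and 2 overlap measures. V gene usage was tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, TMM factors, filterByExpr) on clonotype numbers per V gene. The threshold was an adjusted p of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Alternatives were DESeq2, no TMM, no filter, deposited counts in place of clonotypes, lineages in place of clonotypes, a minimum count of 2, clonotypes by CDR3 amino acids, medians or count-weighted means of mutation frequency, V positions likely to be strain variants left out (a mismatch in over 50% of a V gene's IgM clonotypes), an equal V gene mix, other depths, other lineage identities (85% and 95%), the Jaccard index, each mouse left out, and the replicate number as a block. Alternatives added after the data were seen left out clonotypes with more counts in another mouse (the same V gene, J gene and junction), pairs of consecutive libraries, or IgA, or counted each rearrangement once per class. The other choices, the tests between groups, the B-1 gene list and the rule for named genes were fixed before the data were examined. Tests of explanations that were chosen later are named as such below. The rule names the genes past the threshold, the 5 IGHV genes (3 for IGKV and for IgG) with the smallest p in each direction where fewer pass, the most used genes, the B-1 list, the leading IgG clonotype of each mouse and the 5 IgG clonotypes found in most mice of a group.

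With 20834 to 41260 classed clonotypes per mouse, an IgG share of 0.999% has a 95% interval of 0.904 to 1.10, narrower than the spread between mice. The interval takes clonotypes as independent and covers counting error alone. Sequences with a count of 1 formed 58.4% ± 6.32 of all assembled sequences in isotype mice and 67.7% ± 3.72 in anti-CTLA-4 mice (SD, n = 5 each). The functions were tested on simulated data: all mutation counts of 500 simulated sequences and all 200 simulated lineages were recovered, and 50 permutation p values equalled those of scipy. In counts simulated from the real means, the edgeR step recovered 20 of 20 IGHV genes changed 2-fold among 96 with 1 false call, 19 of 20 IGKV genes among 89 with 1 false call, and 1 of 4 IGHV genes among the 15 tested in IgG with 0 false calls. Each set was simulated once, with the same common dispersion for all its genes, so the recovery does not hold for genes that vary more between mice. In IgG, 2-fold changes were thus mostly missed. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.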

Results

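B cell receptor transcripts were sequenced in bulk from the deep cervical lymph nodes, which receive drainage from the brain and meninges, of 10 C57BL/6 mice carrying GL261 gliomas. GL261 is a mouse glioma cell line, implanted here in the brain, and the nodes were taken on day 20. The mice had received an isotype control IgG (n = 5) or an antibody against CTLA-4 (n = 5), an inhibitory receptor of T cells. One library was made per mouse, so each mouse is 1 replicate. The libraries held 33568 to 63017 assembled receptor sequences and a total deposited count of 382184 to 790139. Productive heavy chains took 158989 to 362371 of those counts and formed 20886 to 41329 clonotypes per mouse, a clonotype being a distinct combination of V gene, J gene, junction and constant gene. The sources used here do not say whether a deposited count is a read or a UMI-collapsed molecule, so binomial intervals and limits below cover counting error only.

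The first question was whether CTLA-4 blockade altered the class composition of the nodes, IgG being the class that dominates serum responses after T cell help. IgG made up 3.26% ± 1.89 (SD, n = 5) of heavy-chain clonotypes in anti-CTLA-4 mice and 1.53% ± 0.626 (SD, n = 5) in isotype mice, a ratio of 2.14. Anti-CTLA-4 replicates 1, 2 and 3, at 3.52%, 5.24% and 4.89%, lay above every isotype mouse, whereas replicate 5 at 1.68% and replicate 4 at 0.999% (95% exact Clopper-Pearson interval 0.904 to 1.10) lay within the isotype range of 0.720% to 2.36%. Each IgG gene had a higher mean after anti-CTLA-4. IgG2a/c, the subclass favoured by type 1 cytokines, averaged 0.811% ± 0.476 against 0.344% ± 0.180, IgG2b 1.11% ± 0.529 against 0.616% ± 0.186, IgG3 0.341% ± 0.207 against 0.155% ± 0.0734, and IgG1 0.728% ± 0.799 against 0.303% ± 0.183 (SD, n = 5 each). Single mice carried much of this: without anti-CTLA-4 replicate 2 the IgG1 difference was 0.0873 percentage points in place of 0.424, and without replicate 3 the IgG2a/c and IgG3 differences were 0.306 and 0.115 in place of 0.467 and 0.185. IgG2b and IgG2a/c may not be cleanly parted. Each of 66 sequences mainly called IgG2c with a count of at least 1000 had identical copies called IgG2b, with a lowest share of 19.5%. With each rearrangement counted once per class, whatever its IgG genes, the IgG difference was 1.18 percentage points in place of 1.74 (exact permutation p = 0.111). The difference in IgG did not pass its test (two-sided exact permutation p = 0.119, Benjamini-Hochberg adjusted p = 0.268 over 9 composition tests). None of the 8 constant genes passed an adjusted p of 0.05 by the exact permutation test, the smallest unadjusted value being p = 0.0873 for IgG2a/c. With 5 mice per group the smallest p that the reassignments can give is 0.00794.

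The remaining classes differed less. IgM, the class of naive B cells, made up 71.9% ± 1.87 of clonotypes after anti-CTLA-4 and 73.4% ± 0.614 after isotype antibody, and IgD, co-expressed with IgM on naive cells, 24.2% ± 3.25 and 24.5% ± 0.661 (SD, n = 5 each). IgA, the mucosal class, was at 0.562% ± 0.312 and 0.567% ± 0.217. IgE averaged 0.130% ± 0.176 and 0.0903% ± 0.118, with 0 of 39723 clonotypes in anti-CTLA-4 replicate 4, which by a floor of 3 counts allows a share of up to 0.00755%. The exact permutation tests for IgM (p = 0.151), IgD (p = 0.841), IgA (p = 0.984) and IgE (p = 0.659) gave no adjusted p under 0.271.

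Weighted by deposited counts, IgG took 50.1% ± 28.8 of the heavy chain after anti-CTLA-4 and 21.6% ± 13.3 after isotype antibody (SD, n = 5 each). Here 4 of 5 anti-CTLA-4 mice, between 41.6% and 79.7%, exceeded the highest isotype mouse at 37.5%, and replicate 4 stood at 9.92%. Among the IgG genes the means lay furthest apart for IgG2a/c, 21.3% ± 16.6 against 6.76% ± 5.54, and the IgA mean was lower, 25.4% ± 21.8 against 47.05% ± 15.95. By the two-sided exact permutation test neither IgG (p = 0.0794, adjusted p = 0.333 over 9 tests) nor IgG2a/c (p = 0.0952, adjusted p = 0.333) nor IgA (p = 0.111, adjusted p = 0.333) passed the threshold. In isotype replicate 4 and anti-CTLA-4 replicate 4, 75.9% and 29.3% of IgG counts lay on rearrangements with more counts in another mouse of the series. Without such rearrangements their IgG shares of counts were 3.96% in place of 11.2% and 7.32% in place of 9.92%, and their IgG shares of clonotypes 0.639% and 0.695%.

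**Figure D1:**
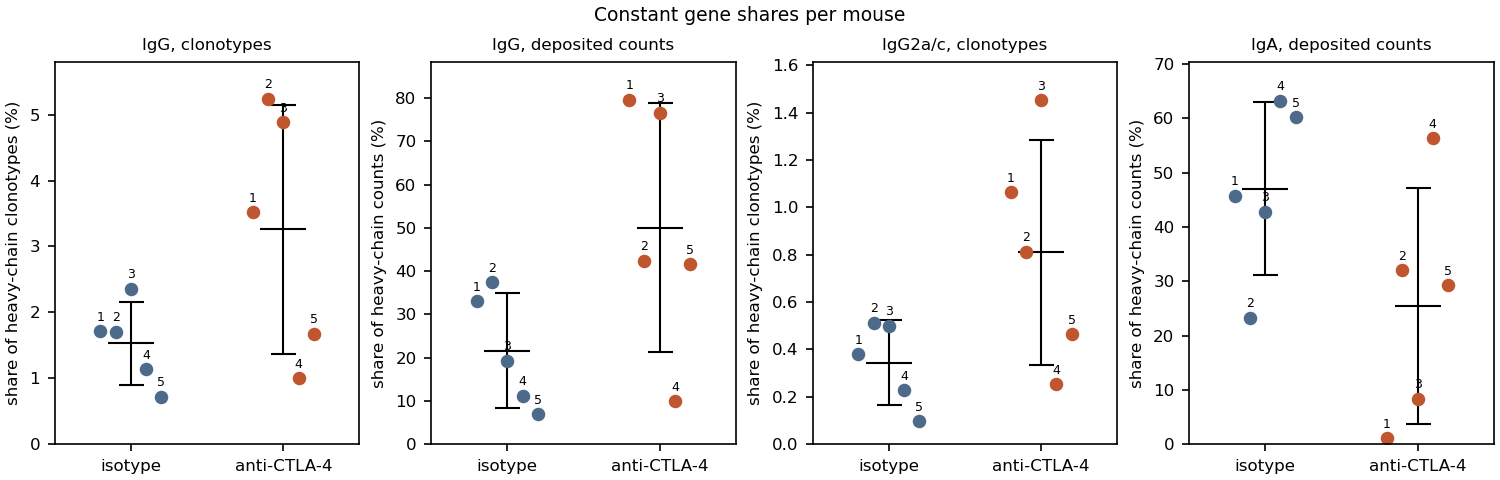
Share of heavy-chain clonotypes or deposited counts (percent, y axes) held by IgG, IgG2a/c and IgA in isotype and anti-CTLA-4 mice; each point is 1 mouse with its replicate number, horizontal bars are means and error bars SD (n = 5 per group). Anti-CTLA-4 replicates 1, 2 and 3 hold IgG clonotype shares of 3.52% to 5.24%, above all isotype mice, and replicate 4 lies at 0.999%.

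Somatic hypermutation, the germinal centre process that introduces point mutations into V regions, was read as mismatches to the germline V gene. IgG clonotypes carried 0.555 ± 0.116 mismatches per 100 V nucleotides after anti-CTLA-4 and 0.715 ± 0.272 after isotype antibody, IgA clonotypes 0.699 ± 0.220 and 0.971 ± 0.146, and IgM clonotypes 0.135 ± 0.0224 and 0.132 ± 0.00266 (SD, n = 5 each). Clonotypes with no V mismatch formed 51.9% ± 6.41 of IgG after anti-CTLA-4 and 43.2% ± 8.29 after isotype antibody. All 5 anti-CTLA-4 mice lay above the isotype mean, which isotype replicate 5 lowered at 28.5%, but only 3 lay above every isotype mouse. Anti-CTLA-4 replicate 1 stood at 43.8%. With clonotypes of a count of at least 2 alone, the unmutated IgG share was higher by 14.3 percentage points (exact permutation p = 0.00794, adjusted p = 0.0476). Over all clonotypes, the lower IgA value (two-sided exact permutation p = 0.0476, adjusted p = 0.286 over 6 mutation tests; below the isotype mean in 4 of 5 anti-CTLA-4 mice) and the higher unmutated share (exact permutation p = 0.0952, adjusted p = 0.286) did not pass after adjustment. IgG and IgM frequencies did not pass either (exact permutation p = 0.270 and p = 0.881). The isotype mean for IgG was raised by replicate 5 at 1.19, while the other isotype mice lay between 0.524 and 0.650. Without that mouse the IgG difference, anti-CTLA-4 minus isotype, was -0.0403 in place of -0.160, and the difference in unmutated share was 5.01 percentage points in place of 8.70 (exact permutation p = 0.198). With all mice but without rearrangements that had more counts in another mouse, the difference in unmutated share was 8.32 percentage points (exact permutation p = 0.151).

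The kind of mutation was compared next. Mismatches at the C or G of AID hotspot motifs, the preferred targets of the mutating enzyme, made up 34.5% ± 6.09 of IgG mismatches after anti-CTLA-4 and 40.0% ± 6.01 after isotype antibody, whereas such positions formed 14.5% of the germline V sequence in both groups. Codon-changing mutations formed 79.9% ± 1.78 and 82.3% ± 4.29 of those in CDR1 and CDR2, the antigen-binding loops, and 67.5% ± 2.47 and 66.9% ± 4.47 of those in framework regions 1 to 3 (SD, n = 5 each). Neither the hotspot share (exact permutation p = 0.190) nor the CDR replacement share (exact permutation p = 0.270) passed the threshold, with an adjusted p = 0.324 for both. With single mice left out, the hotspot difference ranged from -7.57 to -3.56 percentage points and the CDR replacement difference from -3.99 to -1.29. The value of -3.99, without isotype replicate 1, had an exact permutation p = 0.0476 and did not pass after adjustment.

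**Figure D2:**
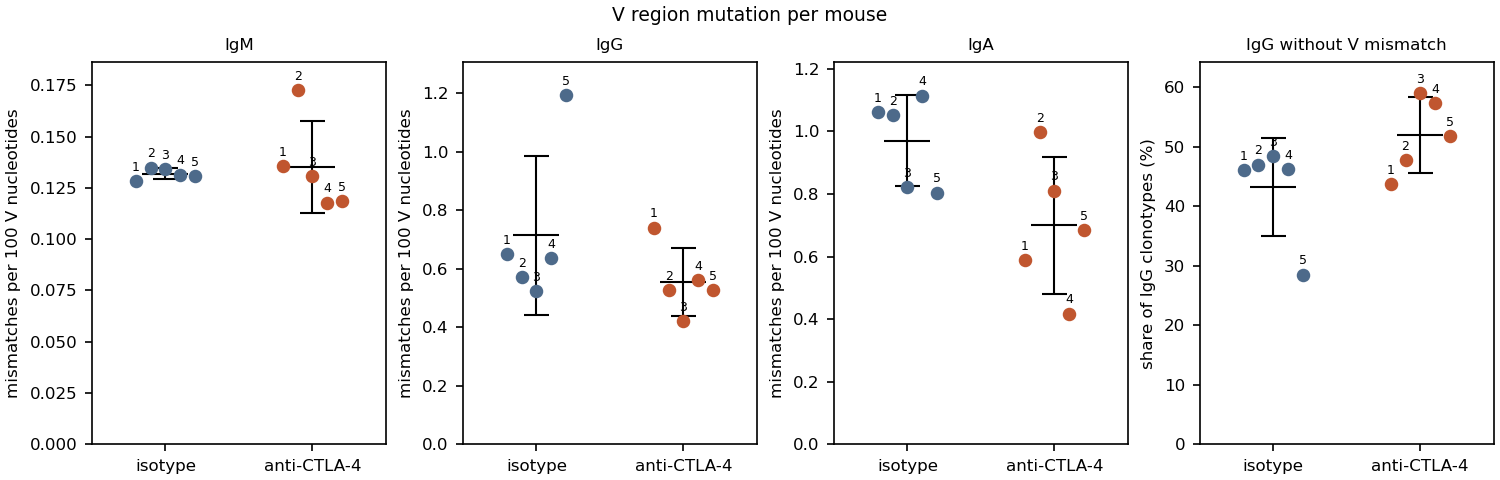
Mismatches per 100 aligned V nucleotides of IgM, IgG and IgA clonotypes and share of IgG clonotypes with no mismatch (percent) per mouse; each point is 1 mouse with its replicate number, horizontal bars are means and error bars SD (n = 5 per group), and the y axes differ in scale. IgG and IgA lie above IgM in every mouse, and isotype replicate 5 stands apart at 1.19 mismatches per 100 nucleotides of IgG.

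The clonal structure of the heavy chain showed no difference past its tests. At an equal depth of 158989 counts, 19688 ± 10140 clonotypes were seen after anti-CTLA-4 and 23200 ± 6268 after isotype antibody, and clonal evenness was 0.553 ± 0.0583 and 0.570 ± 0.0504 (SD, n = 5 each). At the full depth of each mouse, the 10 most abundant clonotypes held 43.5% ± 10.2 and 42.3% ± 5.65 of counts (SD, n = 5 each). Evenness among IgG counts was 0.657 ± 0.0817 and 0.614 ± 0.0618. With single mice left out, its difference ranged from 0.0149 to 0.0627 and that of the clonotype number from -7392 to -1220. The number of lineages that held IgG averaged 246 ± 95.7 and 163 ± 90.8. Of these lineages 47.1% ± 10.5 after anti-CTLA-4 and 35.2% ± 13.5 after isotype antibody also held IgM or IgD, the classes that precede switching, and 48.2% ± 9.04 and 45.6% ± 6.60 held at least 3 distinct sequences. Without isotype replicate 4 the difference in lineages with IgM or IgD was 7.10 percentage points in place of 11.9. In that mouse 58.4% of IgG sequences lay on rearrangements with more counts in another mouse, and in anti-CTLA-4 replicate 4 29.4%. Without such rearrangements their IgG lineages numbered 61 in place of 100 and 117 in place of 171. In 2 families of two-sided exact permutation tests, 4 on diversity and 2 on lineages, the smallest value was p = 0.159 (adjusted p = 0.317) for the share of IgG lineages with IgM or IgD.

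The most abundant IgG clonotype of a mouse held 11.7% to 36.3% of its IgG counts, 24.9% ± 9.00 on average after anti-CTLA-4 and 21.3% ± 4.18 after isotype antibody (SD, n = 5 each). IGHV1-50 with the CDR3 ARMGRAFDY led anti-CTLA-4 replicate 1 with a count of 104534, IGHV1-49 with AREYFDV replicate 3 with 52282, IGHV1-9 with ARERWGFAY replicate 5 with 27230, IGHV1-78 with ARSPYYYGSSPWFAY replicate 2 with 27206, and IGHV3-8 with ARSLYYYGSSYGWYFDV replicate 4 with 2197. Among isotype mice, IGHV2-9 with AKHGSNYVDWYFDV led replicate 2 (18670), IGHV1-50 with ARRGSSPFDY replicate 1 (16392), IGHV10-1 with VRQTTVVPSWYFDV replicates 3 and 4 (9990 and 5415), and IGHV1-15 with TMGVTTGY replicate 5 (3091). Of the 37 heavy-chain sequences with a count of at least 1000 in isotype replicate 3, 32 recurred in replicate 4. The best counted sequence of the leading clonotype had no V mismatch in 9 of 10 mice. IgG2a/c was the main subclass of the leading clonotype in 6 of 10 mice and IgG1 in 3 of 10, among them isotype replicates 3 and 4 with the same clonotype.

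V gene usage, counted in clonotypes, addresses which parts of the germline repertoire the nodes drew on. The IGHV genes with the highest mean share over all mice were IGHV3-6 (4.34%), IGHV1-26 (4.30%), IGHV1-64 (4.13%), the pair IGHV1-62-3 and IGHV1-72, which the files leave unseparated (3.97%), and IGHV9-3 (3.80%); their log2 fold changes, anti-CTLA-4 over isotype, were 0.11, -0.05, -0.09, -0.01 and -0.05. IGHV12-3, a V gene typical of B-1 cells that bind phosphatidylcholine, was the single gene of 96 tested to pass the threshold, with 0.0550% ± 0.0153 of clonotypes after anti-CTLA-4 and 0.0978% ± 0.0236 after isotype antibody (SD, n = 5 each; log2 fold change -0.87 with a standard error of 0.22, adjusted p = 0.0393, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It rested on 224 clonotypes over all mice. The same test called no other gene, 9 genes had an unadjusted p under 0.05, and DESeq2 called 0 genes with 8 under that value. Below IGHV12-3 in rank, IGHV1-49 (log2 fold change 0.75, adjusted p = 0.0522), IGHV10-1 (-0.30, adjusted p = 0.106) and IGHV10-3 (-0.27, adjusted p = 0.106) did not pass the edgeR test. The IGHV12-3 call ended with DESeq2 (log2 fold change -0.85, adjusted p = 0.178), with counts in place of clonotypes (-1.72, adjusted p = 0.0749, edgeR), without clonotypes that had more counts in another mouse (-0.85, adjusted p = 0.0682, edgeR), without any one of isotype replicates 1, 2, 3 and 5 or anti-CTLA-4 replicates 1, 4 and 5 (adjusted p 0.0540 to 0.162, edgeR), and with lineages in place of clonotypes, where the log2 fold change was -0.02 (adjusted p = 0.990, edgeR). IGHV1-49 passed the edgeR test once anti-CTLA-4 replicate 5 was left out (log2 fold change 0.92, adjusted p = 0.0368), and without anti-CTLA-4 replicate 3, whose leading IgG clonotype used this gene, the log2 fold change was 0.46. By edgeR it also passed with the replicate block (0.81, adjusted p = 1.73e-05) and with no filter (0.76, adjusted p = 4.73e-05). The block rests on replicate numbers, which showed no clear pairing of the mice. With DESeq2 IGHV1-49 did not pass (0.83, adjusted p = 0.195). IGHV1-49 stood at 7.73 with counts (adjusted p = 0.0749, edgeR) and 0.42 with lineages (adjusted p = 0.115, edgeR). IGHV10-1 and IGHV10-3 also passed with the replicate block. Of the other genes with the smallest p in each direction, IGHV1-12 (0.19), IGHV5-9-1 (-0.35), IGHV1-85 (-0.20), IGHV1-5 (0.14), IGHV1-9 (0.12) and IGHV1-55 (0.12) did not pass the edgeR test.

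The list of V genes known from B-1 cells, innate-like cells that a node suspension can hold, was fixed in advance. Its 4 heavy-chain members together made up 0.358% ± 0.0106 of clonotypes after anti-CTLA-4 and 0.447% ± 0.0299 after isotype antibody (SD, n = 5 each), with all 5 anti-CTLA-4 mice below all 5 isotype mice. The two-sided exact permutation p = 0.00794 is the smallest the design allows, and it became an adjusted p = 0.143 over the 18 tests of V families and lists, so the difference is reported as not passing. The difference of -0.0890 percentage points was -0.0811 with clonotypes of a count of at least 2 (exact permutation p = 0.151) and -0.0209 in lineages (exact permutation p = 0.159). By class it was -0.0958 in IgM (exact permutation p = 0.00794) and -0.0208 in IgD (exact permutation p = 0.683). On 18 IgG and 6 IgA clonotypes it was -0.450 (exact permutation p = 0.167) and 0.465 (exact permutation p = 0.563). Member by member, IGHV12-3 and IGHV11-2 were lower after anti-CTLA-4 by exact permutation p = 0.0238 and p = 0.0397, and IGHV7-1 (p = 0.349) and IGHV11-1 (p = 0.0714) did not pass; adjusted over the list alone, 0 of 4 members passed, with adjusted p = 0.0794 for the first pair. With edgeR over all genes tested, 1 of the 3 members that could be tested passed: IGHV11-2 had a log2 fold change of -0.24 (adjusted p = 0.654), which reversed to 0.0137 with a count of at least 2 and to 0.0220 with counts in place of clonotypes, and IGHV7-1 of -0.16 (adjusted p = 0.854). The 2 light-chain genes of the list, of which IGKV4-91 is 1, together made up 2.27% ± 0.309 of kappa clonotypes after anti-CTLA-4 and 2.41% ± 0.407 after isotype antibody (exact permutation p = 0.556, n = 5 each). IGKV4-91 had a log2 fold change of -0.12 and the other gene one of 0.06.

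**Figure D3:**
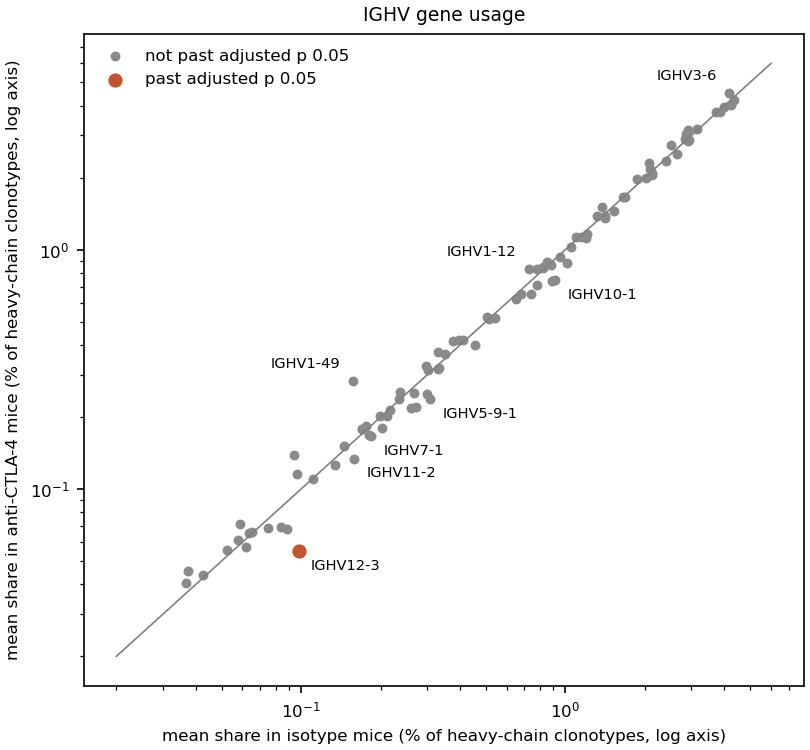
Mean share of each tested IGHV gene in isotype mice (x axis) and anti-CTLA-4 mice (y axis), as a percent of heavy-chain clonotypes on log axes; each point is 1 of 96 genes, the line marks equal shares, and the larger point passed an adjusted p of 0.05. IGHV12-3 lies below the line, at 0.0978% against 0.0550%, and IGHV1-49 lies above it.

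Among IgG clonotypes 15 IGHV genes could be tested and 0 passed the edgeR test; 1 had an unadjusted p under 0.05 with edgeR, 2 with DESeq2, of which 0 passed after adjustment. IGHV1-9 had the smallest p, with 5.74% ± 5.13 of IgG clonotypes after anti-CTLA-4 against 1.18% ± 1.23 (SD, n = 5 each; log2 fold change 2.47, standard error 0.84, adjusted p = 0.0853, edgeR). Without anti-CTLA-4 replicate 5, whose leading IgG clonotype used this gene, its log2 fold change was 1.40. IGHV1-80 reversed from a log2 fold change of -1.45 to 0.44 without isotype replicate 5. IGHV1-18 (log2 fold change 1.40), IGHV1-69 (0.70), IGHV1-80, the pair IGHV1-62-3 and IGHV1-72 (-1.35) and IGHV1-64 (-0.59) had adjusted p values of 0.472 or more by edgeR. With single mice left out, the log2 fold change of IGHV1-18 ranged from 0.65 to 1.55, that of IGHV1-64 from -1.23 to -0.24 and that of the pair from -2.30 to -1.27.

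For the kappa light chain 0 of 89 IGKV genes passed the edgeR test, 3 had an unadjusted p under 0.05, and DESeq2 called 0 with 2 under that unadjusted value. IGKV6-23, IGKV6-15 and IGKV10-96 had the highest mean shares, 3.98%, 3.42% and 2.91% of kappa clonotypes. IGKV6-23 was at 4.62% ± 1.45 after anti-CTLA-4 and 3.35% ± 0.470 after isotype antibody (SD, n = 5 each; log2 fold change 0.51), and IGKV6-32 at 1.64% ± 0.338 and 2.44% ± 1.08 (log2 fold change -0.55), both with adjusted p = 0.910 by edgeR. Without isotype replicate 3 the log2 fold change of IGKV6-32 was -0.24. Within each direction, the next smallest p belonged to IGKV13-85 (0.40) and IGKV9-120 (0.31) among higher genes, and to IGKV8-27 (-0.30) and IGKV3-7 (-0.24) among lower genes. Lambda chains formed 1.86% ± 0.173 of light-chain clonotypes after anti-CTLA-4 and 1.97% ± 0.222 after isotype antibody (exact permutation p = 0.421), and the difference of -0.110 percentage points was -0.0344 without isotype replicate 4.

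The IGHV1 family, the largest of C57BL/6 mice, made up 65.1% ± 0.905 and 64.7% ± 0.377 of clonotypes after anti-CTLA-4 and isotype antibody, and the IGHV10 family 1.48% ± 0.140 and 1.80% ± 0.155 (SD, n = 5 each). IGHV10 was below every isotype mouse in 4 of 5 anti-CTLA-4 mice (exact permutation p = 0.0159, adjusted p = 0.143 over 18 tests). All 5 anti-CTLA-4 mice lay below the isotype mean for the IGHV12 family, 0.0550% ± 0.0153 against 0.0987% ± 0.0247 (exact permutation p = 0.0238, adjusted p = 0.143), and the IGHV11 family, 0.137% ± 0.0194 against 0.166% ± 0.0180 (exact permutation p = 0.0397, adjusted p = 0.179), and neither passed. These families consist almost wholly of IGHV12-3 and IGHV11-2 of the B-1 list, so they repeat the values of those genes and are not separate results. IGHJ1 was at 16.6% ± 0.228 and 16.1% ± 0.349 (exact permutation p = 0.0476, adjusted p = 0.190 over 4 J genes). The mean CDR3 length was 11.8 amino acids for IgM in both groups and, for IgG, 11.8 ± 0.234 after anti-CTLA-4 and 11.5 ± 0.410 after isotype antibody (exact permutation p = 0.143, adjusted p = 0.286 over 2 tests). Without isotype replicate 5 the IgG difference was 0.166 amino acids in place of 0.342.

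Sharing of heavy-chain clonotypes between mice was the second result to pass its test, but libraries were numbered by group. Same-group pairs thus include the consecutively numbered ones, so the test cannot part treatment from library order. The mean Morisita-Horn index of V gene and CDR3 clonotypes was 0.0134 for pairs of mice of the same group and 0.00342 for pairs of different groups, a difference of 0.0100 (exact permutation p = 0.00794, the smallest possible; adjusted p = 0.0159 over 2 tests). Within anti-CTLA-4 mice it was 0.0165 and within isotype mice 0.0104 (exact permutation p = 0.151). That difference of 0.00601 depended on single mice, from 0.00169 without isotype replicate 5 (exact permutation p = 0.802) to 0.0125 without anti-CTLA-4 replicate 5 (exact permutation p = 0.00794). It was 0.0152 with clonotypes of a count of at least 2 (exact permutation p = 0.0317), and the Jaccard index gave an exact permutation p = 0.913. The index was 0.0236 on average for the 8 consecutively numbered pairs of a group and 0.00669 for the other 12 pairs of the same group. Heavy-chain sequences with a count of at least 1000 in 1 mouse recurred base for base in the next-numbered library of its group in 146 of 226 cases (64.6%), though in 0 of 20 and 0 of 18 from replicate 4 to replicate 5 of isotype and anti-CTLA-4 mice. They recurred in 46 of 666 comparisons with libraries of the same group further apart (6.91%) and in 9 of 1395 with libraries of the other group (0.645%). Without consecutively numbered pairs of a group, the difference between same-group and different-group pairs was 0.00327 (exact permutation p = 0.00794). Without rearrangements that had more counts in another mouse, it was 0.000738 (exact permutation p = 0.00794). Rearrangements with equal counts in different mice stayed in, so this value does not part transfer between libraries from other sharing.

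The 5 IgG clonotypes found in most mice of one group each had by far the most counts in replicate 1 of that group. IGHV1-50 with ARMGRAFDY was counted 104534, 3184, 375, 120 and 43 times as IgG in anti-CTLA-4 replicates 1 to 5, and IGHV1-5 with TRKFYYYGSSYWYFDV 74941, 1731, 165, 59 and 64 times. IGHV1-74 with AMGWDYPFAY and IGHV1-75 with ARVHYYVDY were each found in 4 anti-CTLA-4 mice, with 18133, 384, 2, 0 and 29 counts and 12060, 291, 20, 55 and 0 counts in replicates 1 to 5. IGHV3-8 with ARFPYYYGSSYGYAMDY was found in 4 isotype mice, with 11204, 373, 9, 21 and 0 counts in replicates 1 to 5. All 5 clonotypes were found in 0 mice of the opposite group, which transfer between libraries of a group would also give.

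**Figure D4:**
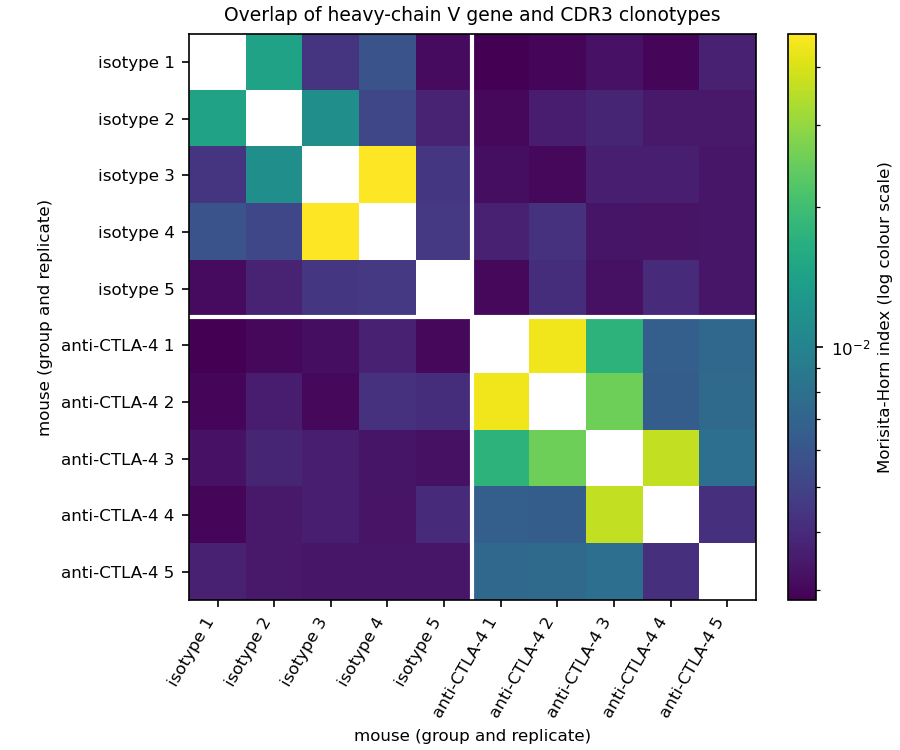
Morisita-Horn index of heavy-chain V gene and CDR3 clonotypes for each pair of mice (log colour scale), with mice ordered by group and replicate number and white lines parting the groups. Values along the consecutive pairs of a group average 0.0236, against 0.00342 between groups, and isotype replicate 5 with anti-CTLA-4 replicate 1 gives 0.00304.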

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

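Chosen after the results were seen were the tests of the same rearrangement in several mice, of IgG2c transcripts read as IgG2b, and of fewer clonotypes per lineage.

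Single mice stood apart from the other 4 of their group in 12 of 110 groups of values, by a gap to the nearest mouse of over 0.71 of the group's range. Chance flags about 1 in 20 groups, or 5.5 of 110. Isotype replicate 5 had the most mutated IgG, with 1.19 mismatches per 100 V nucleotides (0.524 to 0.650 in the other isotype mice), 28.5% of IgG clonotypes without a mismatch (46.0% to 48.4%), an IgG evenness of 0.506 (0.622 to 0.655) and a mean IgG CDR3 length of 10.8 amino acids (11.6 to 11.8). Anti-CTLA-4 replicate 2 had 0.435% of its clonotypes as IgE (0% to 0.111%), 31.3% of its heavy-chain counts as IgG1 (0.550% to 8.85%), and 64.2% of its IgG lineages with at least 3 sequences (42.2% to 46.0%). Anti-CTLA-4 replicate 1 had 14.96% of counts as IgG3 (0.759% to 3.73%) and a heavy-chain evenness of 0.452 (0.560 to 0.595).

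In V families, isotype replicate 4 stood apart at 0.197% for IGHV11 (0.152% to 0.163% in its group), isotype replicate 1 at 6.68% for IGHV14 (6.15% to 6.18%) and anti-CTLA-4 replicate 3 at 0.512% for IGHV15 (0.386% to 0.405%). Outside the B cell receptor, anti-CTLA-4 replicate 2 held 6 counts of T cell receptor beta sequences, above the highest isotype value of 1. No biological explanation was tested for these single mice or for the T cell receptor counts.

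Abundant heavy-chain sequences recurred base for base in the next-numbered library of their group, 64.6% of 226 sequences with a count of at least 1000, against 1.79% of 224 in the previous-numbered library and 0.645% of 1395 in libraries of the other group. The asymmetry argues against the same rearrangement arising in several mice, which has no preferred order. Non-productive rearrangements, which antigen cannot select, recurred in the next library in 60.9% of 69 cases with a count of at least 100 and in 0 of 375 comparisons with the other group, so transfer of material or reads between libraries may be the source. From isotype replicate 3 to replicate 4 the copies held 26.9% as many counts as the originals, and 0.409% to 3.05% in the 5 other pairs that shared any. At which step such transfer would have taken place stays open. Because libraries were numbered by group, transfer would also raise the similarity of mice within a group.

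IgG2c sequences had IgG2b copies of identical sequence: in the 66 sequences led by IgG2c with a count of at least 1000, IgG2b took 19.5% to 49.4% of the IgG2b and IgG2c counts. The upper end is bounded by the choice of sequences led by IgG2c. Mutated sequences do not decide on separate switching by cells of a clone. Of 31 led by IgG2c with at least 2 V mutations and a count of at least 100, 96.8% had an IgG2b copy of at least 10%. Cells that switched after mutating would also give this, and sequences of a clone are not independent. In the other direction, 8 of 32 sequences led by IgG2b had under 5% IgG2c. The IgG2b share of those 32 was 79.0% at the median and 50.2% at the lowest, so most also had IgG2c copies, whose source was not tested. Of 48 sequences led by IgG1 with an IgG1 count of at least 500, 32 had under 5% of another subclass. The rest also had copies called other subclasses. Constant-region reads of IgG2c transcripts may be assigned in part to the similar IgG2b gene, since the lowest IgG2b share of those 66 sequences was 19.5%. However, 1 of the 31 mutated ones had none. Separate switching and chimeric amplification products stay open, and the latter were not tested. With such assignment of reads, IgG2b shares would be too high in both groups, and the IgG share of clonotypes as well. Its difference was 1.18 percentage points with each rearrangement counted once per class and 1.74 with each gene counted.

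The B-1 associated V genes held a smaller share of clonotypes in all 5 anti-CTLA-4 mice than in any isotype mouse. More IgG in the denominator is argued against by IgM clonotypes alone, where the difference was -0.0958 percentage points against -0.0890 over all classes. Clonotypes with more counts in another mouse are argued against as well, since the difference without them was -0.0786. Counted in lineages it was -0.0209 (exact permutation p = 0.159), so fewer clonotypes per lineage of these genes may account for most of it, though linking by junction may also join separate rearrangements. An effect of treatment on B-1 cells stays open, since B-1 cells themselves were not measured.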

How the results depend on the processing

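Chosen after the data were seen were the alternatives that leave out clonotypes with more counts in another mouse, that leave consecutive libraries unpaired, that count each rearrangement once per class, and that leave IgA out of the denominator. Over all alternatives, the results that answer a comparison kept direction and side of the threshold in 377 cases, and were weaker in 12, stronger in 3 and reversed in 8. Single genes and shares kept both in 1025 cases and were weaker in 11, stronger in 7 and reversed in 61. An unchanged side says little, because a lone smallest p adjusts to 0.0714 over 9 tests and 0.143 over 18, and the replicate block gives no permutation p under 0.0625. Where no cause is given below, the cause was not tested.

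The higher IgG share of clonotypes kept its direction under every alternative run, with a difference of 1.24 to 2.30 percentage points with single mice left out, 1.18 with rearrangements counted once per class, 0.546 in lineages and 4.94 with a count of at least 2. By counts the difference was 21.0 to 38.5 with single mice left out, the highest without anti-CTLA-4 replicate 4 (exact permutation p = 0.00794, adjusted p = 0.0714). The unmutated share of IgG passed with clonotypes of a count of at least 2, at 14.3. Overlap within groups missed the threshold with the replicate number as a block, at 0.0100, because sign flips over 5 numbers cannot give a p below 0.0625. Correlations between same-numbered mice over 55 measures lay between -0.0587 and 0.256, which shows no clear pairing by replicate number. Many of these measures depend on each other and single V genes are not among them, so pairing is not excluded. For IGHV genes the block raised the number past the threshold from 1 to 4.

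The number of IGHV genes past the threshold, 1 in the analysis reported, was 0 with a count of at least 2, with counts or lineages in place of clonotypes, without clonotypes that had more counts in another mouse, and with DESeq2; unadjusted p values under 0.05 then numbered 8, 23, 10, 11 and 8. It was 2 with no filter on low counts (IGHV1-49 and IGHV12-3) and 4 with the replicate block (IGHV10-1 and IGHV10-3 in addition), and 0 to 1 with single mice left out. The log2 fold change of IGHV12-3, -0.87 in the analysis reported, was -1.72 with counts, -0.02 with lineages, -0.85 without clonotypes that had more counts in another mouse and -0.85 with DESeq2, so of these the fold itself was lost with lineages alone. With a count of at least 2, IGHV12-3 was too rare to be tested. The mutation frequency of IgM reversed when weighted by counts, at -0.0227, and the share of the top 10 clonotypes reversed at -0.773 without clonotypes that had more counts in another mouse.

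With single mice left out, the IgM mutation difference ranged from -0.00622 to 0.00753, heavy-chain evenness from -0.0277 to 0.00832, the top 10 share from -2.77 to 3.18 and the share of IgG lineages with at least 3 sequences from -1.34 to 5.30. Among class shares of clonotypes, IgD ranged from -1.61 to 0.586, IgA from -0.0914 to 0.0939 and IgE from -0.0363 to 0.0904; by counts, IgG1 from -1.35 to 6.33 and IgE from -4.68 to 0.787. Differences that kept their sign but moved by over 1.5 times were, among others, IgM by clonotypes (-1.87 to -0.817) and by counts (-4.67 to -0.0562), IgD by counts (-2.20 to -0.508), IgG2b by counts (3.43 to 9.00), IgG3 by counts (0.829 to 4.38), IGHV1 (0.130 to 0.717), IGHJ2 (0.0197 to 0.403), IGHJ3 (-0.486 to -0.179) and IGHJ4 (-0.522 to -0.0727). The log2 fold changes of IGHV1-5 (0.0828 to 0.22), IGHV1-55 (0.0708 to 0.17), IGHV7-1 (-0.23 to -0.0845), IGKV9-120 (0.17 to 0.38) and IGKV3-7 (-0.30 to -0.13) did so as well. Among V families, IGHV2 ranged from -0.0499 to 0.0276, IGHV4 from -0.00800 to 0.0523, IGHV14 from -0.289 to 0.155, IGHV16 from -0.00104 to 0.00211 and the B-1 kappa genes from -0.266 to 0.0168. In log2 fold changes, IGHV1-26 ranged from -0.0776 to 0.00898, IGHV1-62-3 with IGHV1-72 from -0.0378 to 0.0233, IGHV9-3 from -0.0722 to 0.0141, IGHV1-69 in IgG from -0.0600 to 0.89, IGHV1-80 in IgG from -2.17 to 0.44, IGKV10-96 from -0.11 to 0.10, IGKV4-91 from -0.21 to 0.0835 and the other B-1 kappa gene from -0.0029 to 0.11.

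With a count of at least 2, reversed differences were 0.482 for IgA, -0.476 for IGHV1, 0.00686 for IGHV2, 0.0394 for IGHV13, 0.371 for IGHV14, -0.000277 for IGHV16, 0.0498 for the B-1 kappa genes, -0.521 for IGHJ2 and 0.0732 for IGHJ3, and reversed log2 fold changes 0.0265 for IGHV9-3, 0.0137 for IGHV11-2 and -0.16 for IGKV10-96. IgA also reversed with clonotypes by CDR3 amino acids (0.0374), with lineages (0.128) and without clonotypes that had more counts in another mouse (0.0165), where the overlap of anti-CTLA-4 minus isotype mice reversed to -0.000371. The log2 fold change of IGHV1-62-3 with IGHV1-72 reversed with lineages (0.0289), without clonotypes that had more counts in another mouse (0.00309) and with no filter (0.000323).

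With counts in place of clonotypes, log2 fold changes reversed for IGHV1-85 (1.10), IGHV3-6 (-0.0608), IGHV1-64 (0.61), IGHV9-3 (0.22), IGHV11-2 (0.0220), IGHV1-80 in IgG (0.31), IGKV6-32 (0.17) and the other B-1 kappa gene (-0.45). IGHV1-80 in IgG reversed with the replicate block (0.13), and IGKV10-96 with no TMM (-0.00793). Usage among IgG lineages left 0 genes to test, and IgA mutation at an equal V gene mix gave no value.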

Other observations

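The clones named here were chosen after their values were seen, and the counts of splits of the mice were planned.

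Deposited counts per clonotype were low for IgM, 2.17 ± 0.375 on average in isotype mice and 2.53 ± 0.948 in anti-CTLA-4 mice, and for IgD, 1.45 ± 0.168 and 1.24 ± 0.0944 (SD, n = 5 each). They were higher for IgA, 680 ± 107 and 373 ± 302, IgG, 112 ± 55.8 and 187 ± 132, and IgE, 411 ± 240 and 155 ± 165 (n = 5 each, but 4 anti-CTLA-4 mice for IgE). The IgE mean exceeded the IgG mean in isotype mice and not in anti-CTLA-4 mice. Within the latter, replicates 2 and 5 had more counts per clonotype for IgE than for IgG, and replicates 1 and 3 fewer. No test was run between classes or groups. Among IgG sequences with a count of at least 1000, 72 of 84 in anti-CTLA-4 mice (85.7%) and 29 of 42 in isotype mice (69.0%) had no V mismatch. Sequences of a mouse are not independent, and this difference was not tested.

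Several leading IgG clones were also read in other classes of the same mouse. IGHV1-50 with ARRGSSPFDY of isotype replicate 1 had 8067 counts as IgM beside 16392 as IgG, IGHV10-1 with VRQTTVVPSWYFDV of isotype replicate 3 had 6428 as IgE beside 9990 as IgG, and IGHV1-78 with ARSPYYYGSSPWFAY of anti-CTLA-4 replicate 2 had 5514 as IgE beside 27206 as IgG. IGHV1-15 with TMGVTTGY of isotype replicate 5 had 2710 counts as IgA beside 3091 as IgG. IgE took 21.1% of the heavy-chain counts of isotype replicate 3, and IGHV1-47 with ALLRFAY alone held 26048 counts, 40.5% of that mouse's IgE.

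Chance cannot be excluded for the single IGHV gene past the threshold: 8 of 100 splits of the 10 mice, the real one included, gave as many genes, and the highest other split gave 2. Among IgG clonotypes and for IGKV, the real split gave 0 genes, so 100 of 100 splits gave as many, and the highest other split gave 1 in both cases.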
